A study of Mus musculus with 12 samples.

How the data were processed

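The series measured RNA from mouse splenic dendritic cells on 12 oligonucleotide arrays. Cells of high CD11c were sorted into CD4+, CD8+ and double-negative (DN) subsets. Each subset was processed at isolation (fresh) or after a culture period (cultured), which gives 6 groups of 2 arrays. Per the labels, the deposited values are Average Difference intensities, to which the authors applied global scaling. The software and its version are not given in the sources used here. The deposited table is on a linear scale and was used without further normalization. After trimming 2% of probe sets at each end, the mean of the remaining 96% was the same on every array, and 19.7% to 26.5% of the values of an array lay below 0. Whether replicates came from separate animals is not stated in the labels. One label of fresh CD8+ replicate 1 calls the cells CD4 positive, while the other labels call them CD8+. Its intensities of Cd8a (1210.4) and Cd4 (92.0) go with CD8+, as which it was used. The p-values measure the spread between these samples, which may be technical.

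The table held 12488 probe sets, of which 66 control probe sets were left out of all tests. Of the other 12422, the platform annotation gave 1 gene symbol to 10833, several to 396 and none to 1193. Probe sets with several symbols were not named. Entrez identifiers of 10817 probe sets were found in the RefSeq gene table, which changed 0 symbols, and the named probe sets covered 8252 distinct symbols. All per-sample columns of the table were used.

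Intensities were put on a generalised log2 scale, log2((x + sqrt(x² + c²)) / 2), which stays defined for values below 0. The offset c was 45.69, the median over arrays of the root mean square of each array's negative values. The detection floor was 91.37, which is 2 times c. Probe sets above the floor on at least 2 of the 12 arrays were tested, which left 6159. For values above 0, differences on this scale understate the change of dim probe sets. Values below 0 can instead inflate a difference. For Klf2 in CD8+ cells, the log2 difference after culture was -7.624, with fresh intensities of 1840.8 and 1272.9 and cultured ones of -63.9 and -55.2. A probe set below the floor on both arrays of a group has only a bound there. For such probe sets the text writes "at least N-fold", the bright group's mean on the log scale against the dim group's mean of, per array, the higher of the floor and the probe set's own value, with the adjusted p of the fit. For arrays, precision is limited by their number, which is 2 per group. The text gives group means of the intensity with the SD over the arrays, and log2 differences with their standard error.

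The fit used limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, so that all groups shared 1 estimate of the spread (6 residual degrees of freedom, median prior degrees of freedom 5.09). Moderated tests used eBayes with an intensity trend and robust estimation, and p-values were adjusted by the Benjamini-Hochberg method over the 6159 probe sets. A probe set with an adjusted p under 0.05 was called. The contrasts were the 3 differences between subsets in the fresh and in the cultured state, the culture effect in each subset, the mean culture effect over the 3 subsets, and the 3 differences in culture effect between subsets. A gene with several probe sets, as 666 genes had among those tested, was represented by the probe set with the highest mean over the arrays. Preparation of the table and the figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

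Gene lists were fixed from general knowledge. The 31 lists covered markers of CD8+ and of CD8-negative dendritic cells, antigen presentation, pattern recognition, maturation, NF-kB targets, immediate-early, heat shock and interferon-induced genes, cell cycle, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, chemokine receptors, adhesion, actin, complement and Fc receptors and apoptosis. They also covered markers of other cells that a spleen preparation can hold, namely T, B, plasma, plasmacytoid dendritic, NK, macrophage, neutrophil, red, platelet, stromal and basophil or mast cells. Lists with at least 5 measured genes, which were 29, were tested with limma's camera against the other genes of the 4722 represented, with a preset inter-gene correlation of 0.01 and adjustment over the lists. The same test with a correlation estimated for each list was an alternative, and its p is printed beside each call. The count of members called over all genes stands beside the count adjusted over the list alone.

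Genes named in the text came from a fixed rule. For the fresh contrasts and the mean culture effect, the rule took the 6 higher and 6 lower called genes of largest log2 difference that were above the floor on all arrays compared, and the 4 higher and 4 lower of largest bound. It added up to 4 members of lowest p from each tested list, 2 from each other list, and the sort antigens Cd4, Cd8a, Cd8b1 and Itgax. For the cultured contrasts and each subset's own culture effect it took the 3 higher and 3 lower of largest log2 difference. Probe sets that can take signal from related transcripts were left out of the size rules. They were kept where a gene came from a list, and those of Cadm1, H2-K1, H2-D1, Gadd45b and Il1r2 are among them. Cd8b1 had no tested probe set.

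The labels number the experiments 1 and 2 in every group, and this number is the source of the pairing that was checked. In 15 of 15 pairs of groups, the arrays of the same number deviated from their group means together, with correlations of 0.106 to 0.444 (median 0.267) across probe sets. In every group, the negative values of replicate 1 had a higher root mean square than those of replicate 2. The 3 arrays with the highest 3' to 5' ratios of the Gapdh control probe sets were also all replicate 1. The check therefore cannot tell paired samples from array or RNA quality that goes with the number. A fit with the number as a block (5 residual degrees of freedom) was an alternative, and the main results came from the fit without it.

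The other alternatives were quantile normalization, scaling to a common 75th percentile, a hard floor with plain log2, the offset at 0.5 and at 2 times its value, no filter, a filter of 6 arrays, eBayes without trend and robust estimation, array weights, a fit of only the groups compared, a threshold of 2-fold added to the adjusted p, and leaving out each array in turn. After the data were seen, a fit of the 6 arrays of the same state, quantile normalization after the filter, and leaving out 3 arrays with a high 3' to 5' ratio of the Gapdh control probe sets were added. The groups, contrasts, gene lists, gene rule and all other alternatives were chosen before the data were examined.

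The fit was tested on simulated data with 200 of 6159 probe sets changed by known amounts, drawn with the spread of the real arrays. For fresh CD8+ against CD4+ cells it recovered 9% of the probe sets changed by 1 on the log2 scale, 41.8% of those changed by 2 and 75.8% of those changed by 3. For the mean culture effect, it recovered 47.8%, 92.5% and 83.3%. In each, 4.5% of the calls were false. The list test called 10 of 10 simulated lists of 20 genes shifted by 0.6 and 0 of 90 lists that were not shifted. The simulated probe sets varied independently of each other. The simulation therefore cannot show how often the preset correlation gives false list calls where genes vary together.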

Results

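Transcript levels of 12422 probe sets were measured in mouse splenic dendritic cells, sorted for high CD11c and separated into CD4+, CD8+ and CD4- CD8- double-negative (DN) cells. RNA was taken at isolation (fresh) or after 2 h of culture at 37 °C (cultured), and 2 arrays were made for each of the 6 groups. The trimmed mean intensity was 150.0 on every array. The noise, taken as the root mean square of an array's values below 0, was 108 on replicate 1 of cultured CD4+ cells and 26.2 to 82.5 on the other 11 arrays. The ratio of the 3' to the 5' Gapdh control probe set, a sign of RNA integrity, was 2.55 on replicate 1 of fresh CD8+ cells. It was 1.97 on replicate 1 of cultured CD4+ cells, 1.34 on replicate 1 of cultured DN cells and 0.890 to 1.04 on the other 9. The same ratio of the actin control probe sets was 0.908, 1.16 and 0.919 on these 3 arrays, in that order. The highest actin ratio, 1.28, was on replicate 2 of cultured CD4+ cells, so the 2 controls did not rank the arrays alike. Rank correlations between replicates were 0.888 to 0.943 in the fresh groups and 0.832 to 0.909 in the cultured groups. Those between different subsets of the same state overlapped them, at 0.8725 to 0.9503 (fresh) and 0.8237 to 0.9213 (cultured). The medians were 0.941 and 0.902 between replicates and 0.925 and 0.881 between subsets, so replicates were only slightly more alike. Between replicates, the share of tested probe sets that differed by more than 2-fold ran from 5.9% in fresh CD4+ cells to 24.7% in fresh CD8+ cells and 36% in cultured CD4+ cells.

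The comparison of fresh CD8+ with fresh CD4+ cells asked which transcripts set the sorted subsets apart before culture. Cd8a, which encodes the CD8 alpha chain used in the sort, had an intensity of 1443 ± 329 in CD8+ cells and 15.4 ± 6.0 in CD4+ cells (SD, n = 2 arrays each), at least 15.6-fold higher (limma, adjusted p = 0.000518). Cadm1, an adhesion molecule of cross-presenting dendritic cells, was higher by 4.59 ± 0.45 on the log2 scale (SE, 3311 ± 20.8 against 134 ± 7.4, adjusted p = 0.000618). The probe set of Cadm1 can take signal from related transcripts. Cd24a, a surface sialoglycoprotein, was higher by 3.56 ± 0.28 (2274 ± 299.5 against 192 ± 38.7, adjusted p = 0.000196). Dtx1, a Notch target, was lower by -4.40 ± 0.28 (99.2 ± 12.9 against 2199 ± 96, adjusted p = 3.92e-05), and Ltb, which encodes lymphotoxin beta, by -2.46 ± 0.29 (835 ± 43.7 against 4618 ± 804, adjusted p = 0.00135). For each of these genes, both CD8+ arrays lay on the same side of both CD4+ arrays, which the gene rule required of those taken by size or bound.

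Further transcripts higher in fresh CD8+ cells were Cxcl9, a chemokine gene (1901 ± 564 against 129.6 ± 0.1, adjusted p = 0.00135), Mpeg1, which encodes a pore-forming protein of phagocytes (5220 ± 2618 against 389 ± 137, adjusted p = 0.000831), and Gusb, a lysosomal enzyme (2115 ± 77.7 against 274 ± 4, adjusted p = 0.000243). Xcr1, the receptor for the chemokine XCL1, was at least 6.24-fold higher (623 ± 353 against 51.2 ± 6, adjusted p = 0.00287). Lower were the interferon-inducible membrane protein gene Ifitm1 (at least 6.52-fold; 65 ± 22.8 against 596 ± 13.3, adjusted p = 0.000831) and Plxnd1, a semaphorin receptor (at least 5.06-fold; 43.2 ± 12.7 against 463 ± 24.8, adjusted p = 0.000707). Relb, an NF-kB subunit, was lower by -2.11 ± 0.23 (393 ± 33 against 1706 ± 129, adjusted p = 0.000961), while its other tested probe set was not called. Irf8, a transcription factor of CD8+ dendritic cells, stood at 6644 ± 2301 against 345 ± 145 (log2 4.28 ± 0.66, adjusted p = 0.00585), but its call was lost without fresh CD4+ replicate 2 (adjusted p = 0.0818) or fresh CD8+ replicate 1 (adjusted p = 0.0715). The antigen receptor modulators Cd22 (at least 5.88-fold lower; 6 ± 12.4 against 538 ± 36.8, adjusted p = 0.0119) and Cd72 (115 ± 52.2 against 771 ± 40.7, adjusted p = 0.017) are best known from B cells. Their calls were lost without fresh CD4+ replicate 1 (adjusted p = 0.206 for Cd22 and 0.135 for Cd72), fresh CD4+ replicate 2 (0.244 and 0.15) or fresh CD8+ replicate 1 (0.0612 and 0.158), and that of Cd22 also without fresh DN replicate 2 (0.0611) and with the offset at 0.5 times its value (0.0617). Cd4 itself had 75.4 ± 23.4 in CD8+ and 615 ± 3.2 in CD4+ cells (log2 -2.93, adjusted p = 0.0903) and was not called. Among other settings, it passed without cultured DN replicate 1 (adjusted p = 0.012) or replicate 2 (0.011), with a hard floor (0.00266) and with the replicate number as a block (0.0488). Itgax, which encodes CD11c, had 1952 ± 710 and 2948 ± 369.8 (log2 -0.64, adjusted p = 0.694).

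**Figure D1:**
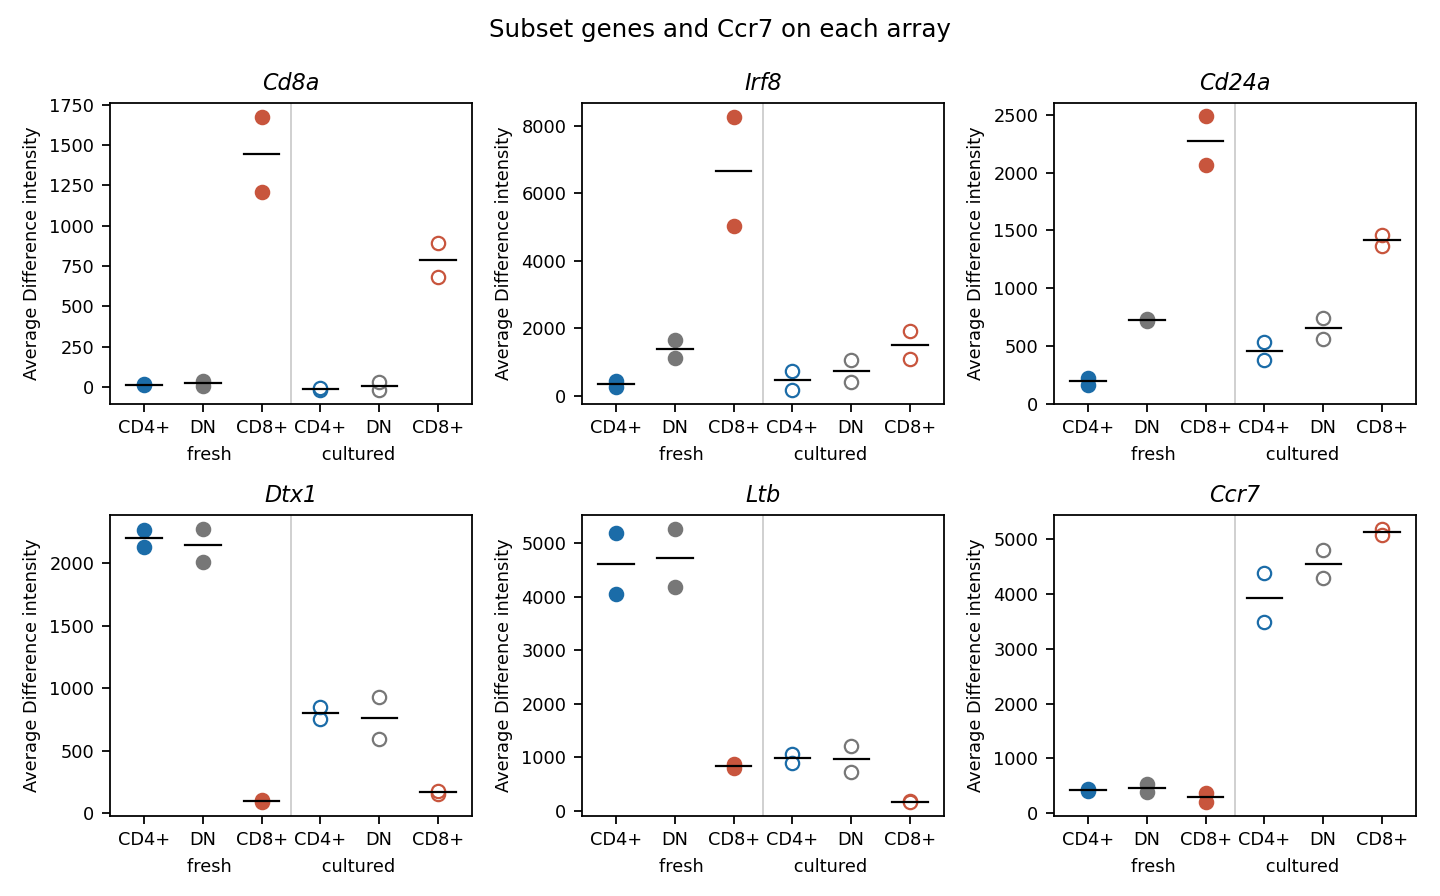
Average Difference intensity (linear axis) of 6 genes on each of the 12 arrays, with filled points for fresh cells, open points for cultured cells and a bar at the mean of each group (n = 2). Fresh CD8+ means were 1443 for Cd8a and 6644 for Irf8, fresh CD4+ and DN means were 2199 and 2146 for Dtx1, and cultured means of Ccr7 were 3928 in CD4+, 5132 in CD8+ and 4543 in DN cells.

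Of 13 measured markers of CD8+ dendritic cells, 9 were higher and 0 lower in fresh CD8+ cells, or 11 and 0 adjusted over the list alone (median log2 3.26). Limma's camera, which tests a list against the other genes, gave adjusted p = 6.54e-22, and adjusted p = 0.00491 with an estimated correlation. Of 17 markers of CD4+ and other CD8-negative dendritic cells, 6 were lower and 0 higher, or 11 and 1 adjusted over the list alone (median -2.08). This list had adjusted p = 2.22e-10, and adjusted p = 0.0197 with an estimated correlation. The first of these lists includes Cd8a and the second Cd4, the antigens that defined the subsets. In every comparison of subsets, the sort itself therefore set part of the result for these lists. NF-kB targets and inflammatory cytokines were lower as a list (34 measured, 3 lower, 0 higher; 5 and 0 adjusted over the list alone; median -0.48). Tested as a list, they had adjusted p = 0.000246, but adjusted p = 0.721 with an estimated correlation. The MHC class II list was lower with 0 of 21 members called, and 2 lower adjusted over the list alone (adjusted p = 0.00743, but adjusted p = 0.721 with an estimated correlation, and 0.0677 without fresh CD4+ replicate 1). Cell cycle genes were lower (43 measured, 1 lower and 0 higher, the same adjusted over the list alone; adjusted p = 0.0208, but adjusted p = 0.721 with an estimated correlation), a call lost without fresh CD4+ replicate 2 (0.322), fresh CD8+ replicate 1 (0.269) or the 3 arrays of high Gapdh ratio (0.216), and with a filter of 6 arrays (0.0962). The oxidative phosphorylation list was higher (44 measured, 0 called in either count, also adjusted over the list alone; adjusted p = 0.0127, but adjusted p = 0.721 with an estimated correlation), a call lost without fresh CD4+ replicate 2 (0.0523) or fresh CD8+ replicate 2 (0.0542). The MHC class I list was higher (13 measured, 0 called, 4 higher adjusted over the list alone). The preset correlation gave adjusted p = 0.0499, but adjusted p = 0.592 with an estimated correlation. Among other settings, that call was lost under quantile normalization (0.163) and without any 1 of fresh CD4+ replicate 2 (0.322), fresh CD8+ replicate 2 (0.347), fresh DN replicate 1 (0.0544), cultured CD4+ replicate 1 (0.0607) or 2 (0.0539), and cultured CD8+ replicate 1 (0.0532) or 2 (0.0523). B cell markers were not called (14 measured, 0 higher, 2 lower, adjusted p = 0.165), and neither were macrophage markers (17 measured, 1 higher, 1 lower, adjusted p = 0.527).

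In all, limma called 122 of 6159 probe sets between fresh CD8+ and CD4+ cells (2%), 63 higher and 59 lower, and 683 had an unadjusted p under 0.05 where chance gives 308. Without the 3 arrays of high Gapdh ratio, 74 were higher and 103 lower. The count was 30 without fresh CD4+ replicate 1, 26 without fresh CD4+ replicate 2, 52 without fresh CD8+ replicate 1, and 200 and 199 without cultured CD4+ replicate 1 or 2. It was 192 with the replicate number as a block, 206 with a hard floor, 189 with quantile normalization after the filter and 75 when only the groups compared were fitted.

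Fresh CD8+ cells were compared with fresh DN cells to ask how far the CD8+ pattern held against the other CD8-negative subset. Cd8a was at least 15.6-fold higher in CD8+ cells (1443 ± 329 against 21.9 ± 20.1, adjusted p = 0.00118). Gusb, the lysosomal enzyme, was higher by 2.42 ± 0.25 (2115 ± 77.7 against 394 ± 13.1, adjusted p = 0.00139), and Pde1b, a cyclic nucleotide phosphodiesterase, at least 8.92-fold (827 ± 199 against 52.5 ± 7.3, adjusted p = 0.00257). Dtx1 was lower by -4.37 ± 0.28 (99.2 ± 12.9 against 2146 ± 187, adjusted p = 4.29e-05). Ifitm1 was at least 8.12-fold lower (743 ± 52.4 in DN cells; adjusted p = 0.00118) and Plxnd1 at least 5.15-fold (472 ± 49.7, adjusted p = 0.0013). Each had both CD8+ arrays on the same side of both DN arrays, which the gene rule required of those taken by size or bound.

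Several further calls were lost when a single array was left out, which leaves 1 array in its group. For each of these genes, both CD8+ arrays still lay on the same side of both DN arrays. Ltb was lower by -2.49 ± 0.29 (adjusted p = 0.00276) and Relb by -1.99 ± 0.23 (adjusted p = 0.00276), and each had an adjusted p of 0.0673 without fresh DN replicate 2. Cadm1 was higher by 3.61 ± 0.45 (adjusted p = 0.00371, and 0.055 without fresh DN replicate 1). S100a4, a calcium-binding protein gene, was lower by -2.71 ± 0.39 (332 ± 156 against 2064 ± 15.7, adjusted p = 0.0063, and 0.0762 and 0.101 without fresh DN replicate 1 or 2).

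Markers of CD8+ dendritic cells were again higher in CD8+ cells (8 of 13, 0 lower; 11 and 0 adjusted over the list alone). As a list, these genes had adjusted p = 2.18e-19, and adjusted p = 0.00693 with an estimated correlation. CD8-negative markers were lower (6 of 17, 0 higher; 10 and 0 adjusted over the list alone). The list test gave adjusted p = 1.85e-12, and adjusted p = 0.0121 with an estimated correlation. NF-kB targets were lower (2 of 34, 0 higher; 6 and 0 adjusted over the list alone; adjusted p = 0.00264, but adjusted p = 0.61 with an estimated correlation), and so were cell cycle genes (1 of 43, 0 higher, the same adjusted over the list alone). Camera gave adjusted p = 0.00264, but adjusted p = 0.444 with an estimated correlation. Without fresh CD8+ replicate 1, whose Gapdh ratio was 2.55, these lists had adjusted p = 0.0578 and 0.143. Without all 3 arrays of high ratio they had 0.0725 and 0.113. Immediate-early genes were lower (0 of 31 called, also adjusted over the list alone). This list had adjusted p = 0.0491, but adjusted p = 0.61 with an estimated correlation. That call was lost with the replicate block (0.0541) and without fresh CD8+ replicate 1 (0.0513) or 2 (0.174), fresh DN replicate 2 (0.16), and cultured DN replicate 1 (0.0639) or 2 (0.0621). It was also lost with a hard floor (0.0875), with the offset at 2 times its value (0.0603) and when only the groups compared were fitted (0.0568).

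The fit called 88 probe sets between fresh CD8+ and DN cells, 38 higher and 50 lower, with 583 at an unadjusted p under 0.05. Among other settings, the balance turned to 72 higher and 62 lower with a hard floor and to 51 and 43 when only the groups compared were fitted. The count was 55 without either fresh CD4+ array, 34 without fresh CD8+ replicate 1, and 11 and 8 without fresh DN replicate 1 or 2, and 161 without the 3 arrays of high Gapdh ratio. Both comparisons used the same CD8+ arrays. They shared 34 higher and 43 lower calls, where independent lists would share 0.39 and 0.48 and simulated unchanged groups against the same CD8+ arrays, in which nothing was set to differ, shared 0. The log2 differences correlated with r = 0.826 (covariance 0.422) over the 6159 probe sets, where those simulated groups gave a median r of 0.741 (covariance 0.225). The simulation drew each array independently. It left out the deviations that fresh arrays of the same experiment number shared (correlations 0.179 to 0.396), so its r is only a rough reference. The shared group of 2 arrays was not split, and part of the excess may come from the shared arrays.

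Fresh DN cells were compared with fresh CD4+ cells to ask whether the CD8-negative subsets differed from each other. Cd4 had 80.2 ± 3.6 in DN and 615 ± 3.2 in CD4+ cells (adjusted p = 1). Cd24a had 720.2 ± 11.3 and 192 ± 38.7 (log2 1.91 ± 0.28, adjusted p = 0.184), and Irf8 had 1381 ± 362 and 345 ± 145 (log2 2.03, adjusted p = 1). Ccr2, a receptor for monocyte chemokines, had 245 ± 110.3 and 20.3 ± 5.7 (adjusted p = 1). None of these passed the threshold. When only the 4 arrays compared were fitted, Cd4 (adjusted p = 0.000223), Cd24a (0.00947), Ccr2 (0.0126) and Irf8 (0.0187) passed. Cd24a also passed with array weights (0.00527), and Cd24a and Cd4 without the 3 arrays of high Gapdh ratio (0.019 each).

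As lists, the CD8+ dendritic cell markers were higher in fresh DN than in fresh CD4+ cells (0 of 13 called, 1 higher adjusted over the list alone; median 0.29). Tested as a list, they had adjusted p = 0.000373, but adjusted p = 0.327 with an estimated correlation. The MHC class II list, which includes H2-Oa (2016 ± 461 against 3093 ± 316, log2 -0.63, adjusted p = 1), was lower (0 of 21 called, also adjusted over the list alone; median -0.30). The preset correlation gave adjusted p = 0.00326, but adjusted p = 0.701 with an estimated correlation, and 0.0789 without fresh CD4+ replicate 1. Immediate-early genes, among them Nr4a2 (232 ± 51.7 against 85.3 ± 0.1, adjusted p = 1), were higher (0 of 31 called, 1 higher adjusted over the list alone). As a list, these genes had adjusted p = 0.01, but adjusted p = 0.701 with an estimated correlation, and 0.137 without fresh DN replicate 2. Interferon-induced genes were lower (0 of 25 called, also adjusted over the list alone). The list test gave adjusted p = 0.01, but adjusted p = 0.738 with an estimated correlation, 0.108 without fresh DN replicate 2 and 0.0538 with a hard floor. Cholesterol synthesis genes, among them Sqle (159.5 ± 17.5 against 75.4 ± 12.9, adjusted p = 1), were higher (0 of 10 called, also adjusted over the list alone). Camera gave adjusted p = 0.0305, but adjusted p = 0.562 with an estimated correlation, and 0.0715 and 0.418 without fresh CD4+ replicate 1 or fresh DN replicate 1. That call was also lost with a hard floor (0.448), a filter of 6 arrays (0.0829), only the groups compared (0.0631) and the 6 arrays of the same state (0.0647). B cell markers were lower (0 of 14 called, also adjusted over the list alone). This list had adjusted p = 0.0329, but adjusted p = 0.701 with an estimated correlation, and 0.0675 and 0.169 without fresh CD4+ replicate 2 or fresh DN replicate 2. A hard floor (0.13) and leaving out the 3 arrays of high Gapdh ratio (0.0511) also ended this call.

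Between fresh DN and CD4+ cells limma called 0 probe sets (smallest adjusted p = 0.184), with 81 at an unadjusted p under 0.05. A fit of only the 4 arrays called 15 and array weights called 1, while the replicate block, the 6 fresh arrays alone and eBayes without trend called 0. Leaving out the 3 arrays of high Gapdh ratio gave 2.

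Culture was compared with the fresh state, as a mean over the 3 subsets, to ask what a short period in culture did to these cells. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 3.58 ± 0.18 on the log2 scale (4534 ± 631 in cultured and 389 ± 105 in fresh cells, SD over 6 arrays each, which mix subsets; adjusted p = 3.79e-07). Cd83, a maturation marker, rose by 2.00 ± 0.15 (7794 ± 1589 against 1961 ± 444, adjusted p = 5.02e-06). Lilr4b, an immunoglobulin-like receptor gene, rose by 4.27 ± 0.22 (3261 ± 653 against 177 ± 84.2, adjusted p = 5.18e-07). Sqstm1, an autophagy adaptor, rose by 3.63 ± 0.13 (7813 ± 2453 against 632 ± 209, adjusted p = 3.61e-08), as did Txnrd1, thioredoxin reductase, by 3.86 ± 0.14 (3738 ± 203 against 258 ± 44.6, adjusted p = 3.61e-08). Rhob, a small GTPase, fell by 2.65 (SE 0.16; 251 ± 115 against 1436 ± 159, adjusted p = 1.24e-06), and Egr1, an immediate-early transcription factor, fell by 2.48 (SE 0.35; 432 ± 224 against 2171 ± 452, adjusted p = 0.000319). Each of these genes moved the same way in all 3 subsets, which the gene rule required of those taken by size or bound.

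Maturation and costimulation genes rose as a list, with 19 of 23 higher and 0 lower, or 20 and 0 adjusted over the list alone (median log2 2.00). Tested as a list, they had adjusted p = 1.01e-11, but adjusted p = 0.281 with an estimated correlation. They included Traf1, a TNF receptor adaptor (2.32 ± 0.15, adjusted p = 1.86e-06), and Tnfsf4, the OX40 ligand (at least 4.08-fold, adjusted p = 3.16e-06). NF-kB targets and inflammatory cytokines rose, with 27 of 34 higher and 0 lower, or 28 and 0 adjusted over the list alone (median 1.34). The preset correlation gave adjusted p = 6.31e-12, but adjusted p = 0.323 with an estimated correlation. Among them, Il1rn, the interleukin-1 receptor antagonist, was at least 9.53-fold higher (adjusted p = 5.24e-06), and Gadd45b, a stress-induced gene, rose by 2.88 ± 0.22 (6495 ± 1926 against 885 ± 262, adjusted p = 6.72e-06). Interferon-induced genes rose, with 14 of 25 higher and 0 lower, or 15 and 1 adjusted over the list alone (median 1.46). As a list, these genes had adjusted p = 5.37e-06, but adjusted p = 0.677 with an estimated correlation. The antiviral gene Rsad2 was at least 10.99-fold higher (adjusted p = 3.32e-05), the chemokine gene Cxcl10 at least 10.4-fold (adjusted p = 4.75e-05) and Ifit1 at least 5.25-fold (adjusted p = 1.77e-05).

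Cell cycle and DNA replication genes fell, with 33 of 43 lower and 2 higher, or 35 and 2 adjusted over the list alone (median -1.43). The list test gave adjusted p = 7.17e-08, but adjusted p = 0.281 with an estimated correlation. Ccnb2, a mitotic cyclin, fell by 1.85 (SE 0.16; 249.8 ± 23.3 against 920.0 ± 197, adjusted p = 1.33e-05), the cyclin gene Ccnd3 fell (98.7 ± 33.7 against 391 ± 40.7, adjusted p = 3.1e-05), and the mitotic kinase gene Cdk1 was at least 2.65-fold lower (adjusted p = 2.15e-05). Cdkn1a, which encodes the cell cycle inhibitor p21, rose (1424 ± 509.6 against 92.4 ± 41.6, adjusted p = 7.27e-07). Cholesterol synthesis genes rose as a list (4 of 10 higher, 1 lower; 5 and 1 adjusted over the list alone). Camera gave adjusted p = 0.0273, but adjusted p = 0.323 with an estimated correlation, 0.0618 without cultured CD4+ replicate 2 and 0.0845 with a filter of 6 arrays. The ribosomal protein list was higher (6 of 23 higher, 1 lower, the same adjusted over the list alone; adjusted p = 0.0273, but adjusted p = 0.677 with an estimated correlation) and turned to the opposite direction, not called, under quantile normalization (adjusted p = 0.341, and 0.331 after the filter). Its call was also lost without fresh CD4+ replicate 2 (0.0781), fresh DN replicate 2 (0.0662), cultured CD4+ replicate 2 (0.0962) or cultured DN replicate 2 (0.0565). The MHC class I heavy chain gene H2-K1 was higher by 0.77 ± 0.15 (adjusted p = 0.0022) and H2-D1 by 0.63 ± 0.14 (adjusted p = 0.00439), but under quantile normalization these turned to -0.012 and -0.14. The probe sets of both genes can take signal from related transcripts, so the values may not be those of 1 gene.

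**Figure D2:**
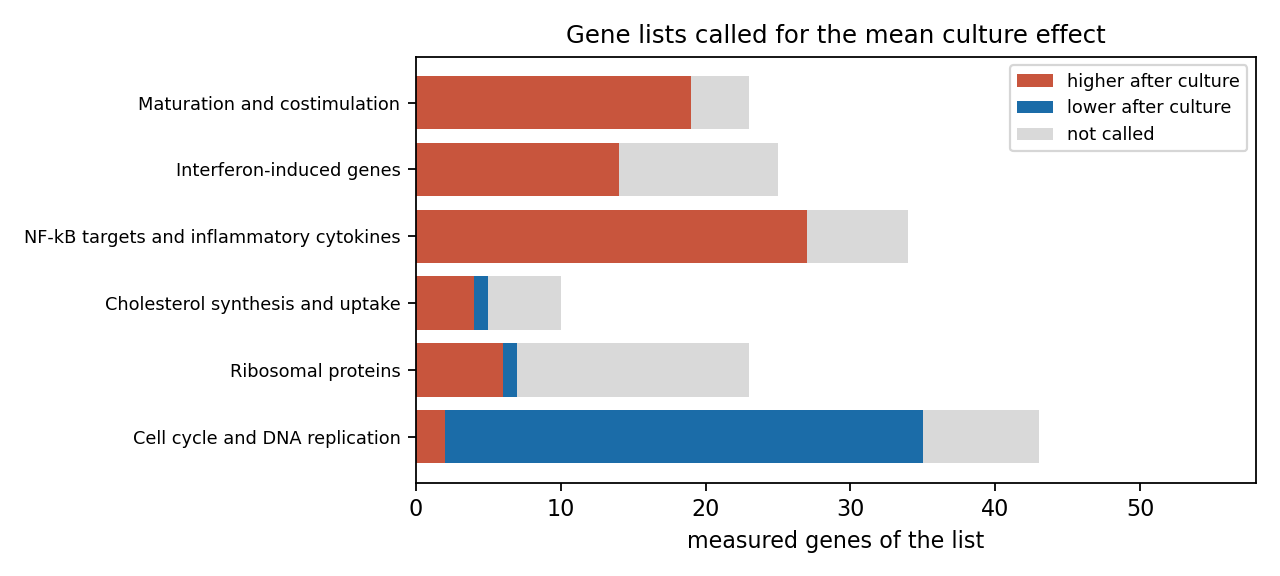
Number of measured genes (horizontal axis) called higher, called lower or not called for the mean culture effect in each of the 6 gene lists that passed the list test with the preset correlation. NF-kB targets had 27 of 34 genes higher and cell cycle genes 33 of 43 lower, while the ribosomal protein list (6 of 23 higher) turned to the opposite direction under quantile normalization, and 0 of the 6 lists passed with an estimated correlation.

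For the mean culture effect, 2420 of 6159 probe sets were called (39.3%), 1047 higher and 1373 lower, so that 56.7% of the calls were lower, and 3056 had an unadjusted p under 0.05. That excess of lower calls depended on the scaling, with 1197 higher and 1211 lower (50.3%) after scaling to a common 75th percentile. The actin 3' control probe set, which was not among those tested, had intensities of 4972 to 10057 on fresh and 13658 to 26808 on cultured arrays. With at least 2-fold also required, the count was 1428.

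The culture effect was then taken in each subset by itself, to ask whether the subsets responded alike. In CD4+ cells, Lilr4b rose by 5.07 ± 0.39 (3642 ± 483 against 103 ± 7.9, n = 2 each; adjusted p = 3.55e-05), the costimulatory ligand gene Cd86 rose by 4.07 ± 0.39 (1896 ± 952 against 101 ± 6.6, adjusted p = 0.000154), and Mapk14, the p38 kinase, fell by 3.20 (SE 0.31; 284 ± 45.8 against 2603 ± 70.2, adjusted p = 0.000154). In CD8+ cells, Procr, the protein C receptor, rose by 4.22 ± 0.24 (7427 ± 17.2 against 398 ± 36.8, adjusted p = 1.19e-05), Ccr7 rose by 4.18 ± 0.31 (5132 ± 83 against 293 ± 120.1, adjusted p = 4.42e-05), and Mycl, a MYC family transcription factor, fell by 3.40 (SE 0.40; 136 ± 42.8 against 1461 ± 287, adjusted p = 0.000713). In DN cells, Procr rose by 3.85 ± 0.24 (2955 ± 576 against 201 ± 22.5, adjusted p = 1.5e-05) and Jun, an immediate-early transcription factor, fell by 3.25 (SE 0.46; 128 ± 23.5 against 1331 ± 660.2, adjusted p = 0.00198).

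Across the 6159 probe sets, which are not independent replicates, the culture effects of CD4+ and CD8+ cells correlated with r = 0.67 (Spearman rho 0.632), those of CD4+ and DN cells with r = 0.816 (0.795) and those of CD8+ and DN cells with r = 0.728 (0.702). No array was shared between subsets. Probe sets called in both with the same sign numbered 338 for CD4+ and CD8+ cells (92.2 for independent lists), 492 for CD4+ and DN cells (112) and 292 for CD8+ and DN cells (49.6), and 0 were called with opposite signs in each pair. Without fresh CD8+ replicate 2 the first correlation was 0.419.

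By limma, culture called 1133 probe sets in CD4+ cells (18.4%; 464 higher, 669 lower; 150 and 104 when only the groups compared were fitted). That count was 363 and 306 without fresh CD4+ replicate 1 or 2, 655 without cultured CD4+ replicate 1, 2102 without cultured CD4+ replicate 2, 717 with array weights and 1786 with the replicate block. In CD8+ cells 501 were called (247 higher, 254 lower; 289 and 188 after scaling to a common 75th percentile). That count was 323 and 316 without fresh CD4+ replicate 1 or 2, 280 without fresh CD8+ replicate 1, 773 and 758 without cultured CD4+ replicate 1 or 2, 131 and 222 without cultured CD8+ replicate 1 or 2, and 969 without the 3 arrays of high Gapdh ratio. In DN cells 610 were called (259 higher, 351 lower). That count was 404 and 397 without fresh CD4+ replicate 1 or 2, 201 and 90 without fresh DN replicate 1 or 2, 964 and 963 without cultured CD4+ replicate 1 or 2, 148 without cultured DN replicate 1, 1172 with array weights, 1178 with only the groups compared and 1039 with the replicate block.

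The difference in culture effect between subsets was tested directly, to ask which responses depended on the subset. No single gene passed, so only values are given. They are of members picked from the cholesterol and NF-kB lists, and not every member went the same way. Ebp of the cholesterol list had a log2 culture effect of -2.03 in CD4+ and -0.951 in CD8+ cells. Tnfaip2 of the NF-kB list had 5.10 and 3.80. Idi1, an enzyme of sterol synthesis, had 43 ± 2.1 in fresh and 489 ± 37.1 in cultured CD4+ cells, 100.4 ± 11.9 and 481 ± 155 in DN cells, and 65.2 ± 63.3 and 61.1 ± 4.9 in CD8+ cells (SD, n = 2 each). Sqle, squalene epoxidase, had 75.4 ± 12.9 and 398 ± 6 in fresh and cultured CD4+ cells, 159.5 ± 17.5 and 415 ± 29.3 in DN cells, and 110.2 ± 6.6 and 128 ± 6.2 in CD8+ cells. Hmgcs1, which makes HMG-CoA, had 188 ± 19.1 and 538 ± 171 in CD4+ cells, 274 ± 67.1 and 923 ± 32.6 in DN cells, and 157 ± 72.3 and 203 ± 47.9 in CD8+ cells. Relb had 393 ± 33 and 1311 ± 7.5 in fresh and cultured CD8+ cells, 1706 ± 129 and 1494 ± 116 in CD4+ cells, and 1568 ± 236 and 1821 ± 171 in DN cells. Bcl3, an NF-kB regulator, had 80.4 ± 4.4 and 394 ± 86.9 in CD8+ cells, 291 ± 35.5 and 199.9 ± 45.9 in CD4+ cells, and 302 ± 66.1 and 359 ± 47.4 in DN cells.

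**Figure D3:**
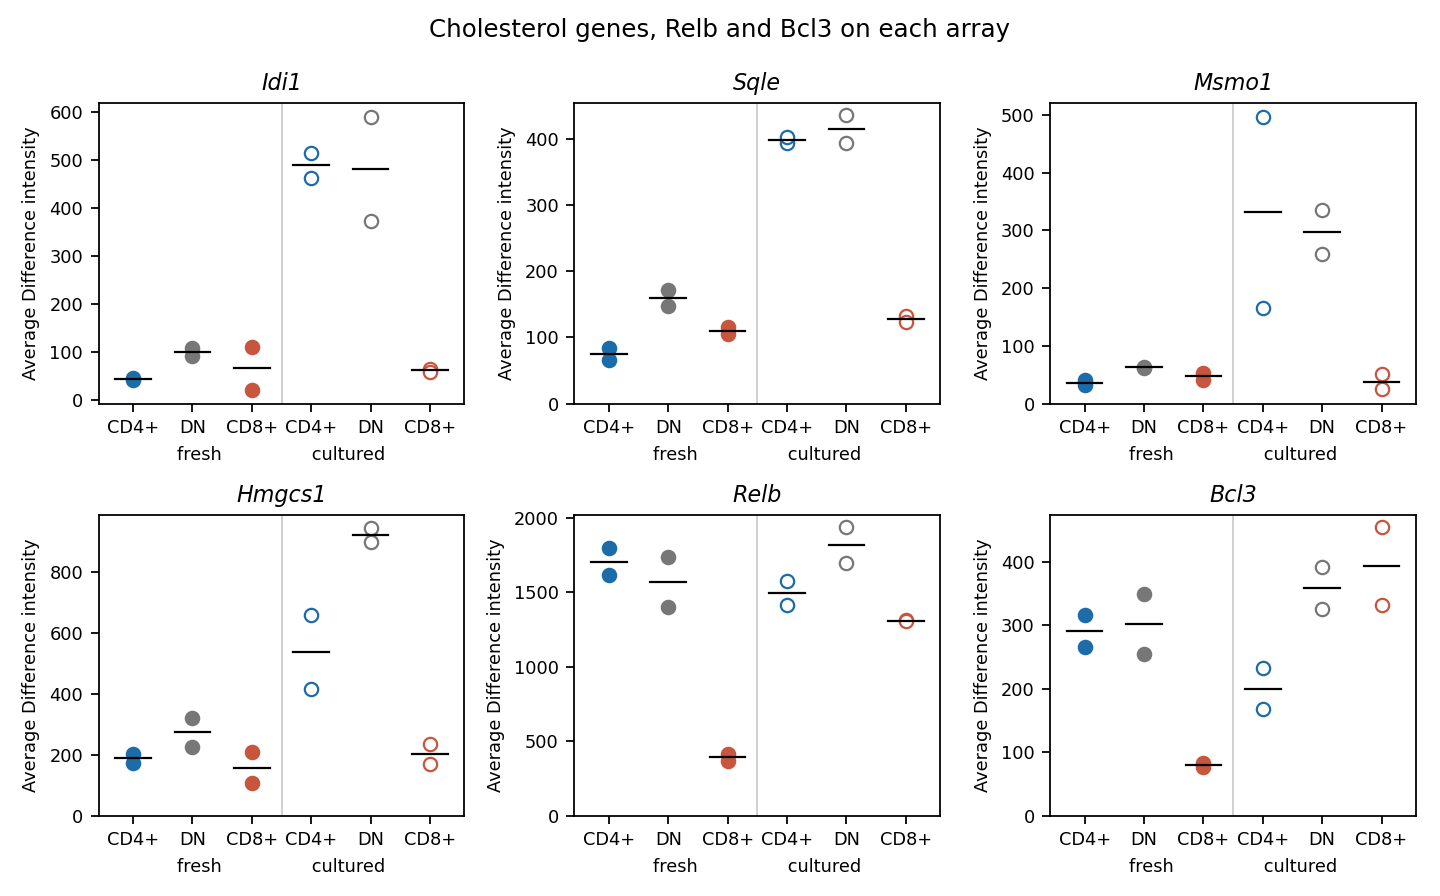
Average Difference intensity (linear axis) of 4 cholesterol synthesis genes, Relb and Bcl3 on each of the 12 arrays, with filled points for fresh cells, open points for cultured cells and a bar at the mean of each group (n = 2). Cultured means of Sqle were 398 in CD4+, 415 in DN and 128 in CD8+ cells, and fresh means of Relb were 1706, 1568 and 393 in the same order.

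As a list, cholesterol synthesis genes had a lower culture effect in CD8+ than in CD4+ cells (0 of 10 called, 3 lower and 0 higher adjusted over the list alone; median difference in log2 effect -1.03). This list had adjusted p = 0.000481, but adjusted p = 0.218 with an estimated correlation. The same held against DN cells (0 of 10 called, 3 lower and 0 higher adjusted over the list alone; median -1.26). Tested as a list, they had adjusted p = 7.79e-06, but adjusted p = 0.107 with an estimated correlation. The culture effect on NF-kB targets, of which 3 were lower in fresh CD8+ than in fresh CD4+ cells, was larger in CD8+ than in CD4+ cells (0 of 34 called, 4 higher adjusted over the list alone; median 0.53; adjusted p = 0.000566, but adjusted p = 0.855 with an estimated correlation) and than in DN cells (0 called, 2 higher adjusted over the list alone; median 0.63). The preset correlation gave adjusted p = 7.79e-06, but adjusted p = 0.744 with an estimated correlation. These NF-kB calls were lost without cultured CD4+ replicate 2 (0.347) and without cultured DN replicate 2 (0.397), in turn.

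For the difference between CD8+ and CD4+ cells limma called 0 probe sets (smallest adjusted p = 0.307; 525 at an unadjusted p under 0.05), for that between CD8+ and DN cells 0 (0.426; 250) and for that between DN and CD4+ cells 0 (0.999; 127). Without cultured CD4+ replicate 2 the counts were 163, 2 and 72, without cultured DN replicate 2 the last 2 were 3 and 1, and without fresh CD8+ replicate 2 the middle one was 1. Plain eBayes gave 1, 1 and 0, leaving out the 3 arrays of high Gapdh ratio gave 7, 0 and 1, and array weights, the groups compared alone and the replicate block gave 0 for each.

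Cultured subsets were compared with each other to ask which subset differences were present after culture. Cd81, a tetraspanin gene, was higher in cultured CD8+ than in cultured CD4+ cells by 3.96 ± 0.40 (3248 ± 47.9 against 212 ± 67.3, n = 2 each; adjusted p = 0.000738) and higher than in cultured DN cells by 3.84 ± 0.40 (229 ± 68.9, adjusted p = 0.00265). S100a4 was lower in cultured CD8+ than in CD4+ cells by -3.66 ± 0.39 (153 ± 15.6 against 1993 ± 402, adjusted p = 0.00106). Gusb was higher in cultured CD8+ than in DN cells by 3.32 ± 0.25 (1757 ± 50.3 against 174 ± 29.9, adjusted p = 0.000272). Ltb was lower in cultured CD8+ than in CD4+ cells by -2.48 ± 0.29 (171 ± 9.8 against 976 ± 115, adjusted p = 0.00143, but 0.0555 when only the 4 arrays compared were fitted).

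Between cultured CD8+ and CD4+ cells, CD8+ dendritic cell markers were higher (6 of 13, 0 lower; 10 and 0 adjusted over the list alone; adjusted p = 4.01e-11, and adjusted p = 0.0314 with an estimated correlation) and CD8-negative markers lower (5 of 17, 0 higher; 8 and 0 adjusted over the list alone). As a list, these genes had adjusted p = 8.39e-08, and adjusted p = 0.0416 with an estimated correlation. Cholesterol synthesis genes were lower (3 of 10, 0 higher; 6 and 0 adjusted over the list alone). The list test gave adjusted p = 0.000115, but adjusted p = 0.0568 with an estimated correlation. MHC class I genes were higher (2 of 13, 0 lower; 8 and 0 adjusted over the list alone). Camera gave adjusted p = 8.25e-05, but adjusted p = 0.0568 with an estimated correlation. Against cultured DN cells, the same 4 lists were called in the same directions: CD8+ markers (adjusted p = 7.99e-12), CD8-negative markers (1.1e-08), MHC class I (4.54e-06) and cholesterol synthesis (2.78e-07), with adjusted p = 0.0215, 0.0215, 0.0277 and 0.0215 with an estimated correlation. Their called members were 4 higher, 6 lower, 1 higher and 5 lower, or 8, 8, 5 and 6 adjusted over the list alone, and 0 went the other way in each.

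The fit called 141 probe sets between cultured CD8+ and CD4+ cells (87 higher, 54 lower; 940 at an unadjusted p under 0.05). Without the 3 arrays of high Gapdh ratio the balance turned to 149 higher and 170 lower. The count of 141 was 88 and 86 without fresh CD4+ replicate 1 or 2, 93 without fresh DN replicate 1, 551 without cultured CD4+ replicate 2, and 35 and 28 without cultured CD8+ replicate 1 or 2. It was 30 with array weights (21 higher, 9 lower), 20 with only the groups compared (13 and 7) and 30 with the 6 cultured arrays alone. Between cultured CD8+ and DN cells 80 were called (40 higher, 40 lower; 50 and 32 after scaling to a common 75th percentile, 28 and 39 with a filter of 6 arrays). That count was 50 and 49 without fresh CD4+ replicate 1 or 2, 158 and 152 without cultured CD4+ replicate 1 or 2, 12 and 5 without cultured CD8+ replicate 1 or 2, 31 and 34 without cultured DN replicate 1 or 2, and 128 with the replicate block. It was 182 with array weights, 30 with only the groups compared, 4 with the 6 cultured arrays alone and 222 without the 3 arrays of high Gapdh ratio. Between cultured DN and CD4+ cells limma called 0 (smallest adjusted p = 0.374; 235 at an unadjusted p under 0.05), but 197 without cultured CD4+ replicate 2, 4 without cultured DN replicate 2, 3 without the 3 arrays of high Gapdh ratio, 1 with a hard floor, and 0 with array weights, the replicate block or the groups compared alone. Of the 122 probe sets called between fresh CD8+ and CD4+ cells, 116 (95.1%) had the same sign after culture and 44 were called in both states, where independent lists would share 2.8. Against DN cells, 84 of 88 had the same sign and 41 were called in both (1.1 for independent lists). Over all 6159 probe sets, the fresh and cultured differences correlated with r = 0.274 (rho 0.113) for CD8+ against CD4+ cells and 0.41 (0.301) for CD8+ against DN cells. These were 0.515 and 0.514 without fresh CD8+ replicate 1, and 0.034 and 0.197 without fresh CD8+ replicate 2. The first was 0.401 and 0.112 without cultured CD4+ replicate 1 or 2, and 0.451 without the 3 arrays of high Gapdh ratio.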

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

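The 8 list results given first were singled out because a gene list's culture effect differed between subsets by the test of the difference itself. The test of the split of the arrays was planned, and the tests on B cell markers, RNA quality and the fit of 4 arrays were chosen after the result was seen. Members called over all genes were 0 in each of the 8 lists.

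The CD8+ dendritic cell markers had a lower culture effect in CD8+ than in CD4+ cells (median difference -0.91, adjusted p = 0.0236, but adjusted p = 0.56 with an estimated correlation; 1 lower and 0 higher adjusted over the list alone). That call was lost without fresh CD8+ replicate 2 (0.262), cultured CD4+ replicate 1 (0.34) or cultured CD8+ replicate 2 (0.0627). It was also lost without the 3 arrays of high Gapdh ratio (0.269), with a filter of 6 arrays (0.317) and with the offset at 0.5 times its value (0.0932). Cd8a, Itgae and Xcr1 of this list lay below the floor on both fresh CD4+ arrays and above it on both fresh CD8+ arrays. A fall of these genes could not be measured in CD4+ cells, so for them the test cannot tell a different response from the floor. NF-kB targets had a higher effect in CD8+ than in CD4+ cells (median 0.53, adjusted p = 0.000566, but adjusted p = 0.855 with an estimated correlation; 0.347 without cultured CD4+ replicate 2) and than in DN cells (median 0.63, adjusted p = 7.79e-06, but adjusted p = 0.744 with an estimated correlation; 0.397 without cultured DN replicate 2). Heat shock genes had a lower effect in CD8+ than in CD4+ cells (median -0.51, adjusted p = 0.00428, but adjusted p = 0.56 with an estimated correlation; 0.262 without fresh CD8+ replicate 2 and 0.122 without cultured CD4+ replicate 2; 0 members adjusted over the list alone). Cell cycle genes had a higher, that is less negative, effect in CD8+ than in CD4+ cells (median 0.58, adjusted p = 0.00202, but adjusted p = 0.56 with an estimated correlation; 0.15 without the 3 arrays of high Gapdh ratio; 1 higher adjusted over the list alone). Cholesterol synthesis genes had a lower effect in CD8+ than in CD4+ cells (median -1.03, adjusted p = 0.000481, but adjusted p = 0.218 with an estimated correlation) and than in DN cells (median -1.26, adjusted p = 7.79e-06, but adjusted p = 0.107 with an estimated correlation), and no setting run other than the estimated correlation ended either call. Immediate-early genes had a lower effect in DN than in CD4+ cells (median -0.43, adjusted p = 0.00167, but adjusted p = 0.981 with an estimated correlation; 0.643 without cultured CD4+ replicate 1 and 0.379 without the 3 arrays of high Gapdh ratio; 0 members adjusted over the list alone).

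For the mean culture effect, 100 of the 462 splits of the 12 arrays into 6 and 6 were drawn. Each was fitted as 2 groups with the subset also in the model. This differs from the main fit of 6 group means, which called 2420 probe sets. The real split called 2510 probe sets, and 1 of the 100 splits, the real one itself, called as many. Chance is therefore an unlikely source of this count, although 1 in 100 was the smallest share that the draw could give. The highest of the others called 2062 and placed 10 of the 12 arrays as the real one does, while the median of the others was 0. Of the splits drawn, 41 had equal numbers of both experiments on each side, as the real one has, and the highest other of those called 0. The split by experiment number called 3.

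Cd22 and Cd72, both known from B cells, were lower in fresh CD8+ than in fresh CD4+ cells. B cells left among the sorted CD4+ cells would bring their other abundant transcripts too, but the other 12 measured B cell markers had a median log2 difference of -0.004 (quartiles -0.523 and 0.574; 6 higher, 6 lower, 0 called), and Ighm had 3447 ± 556 in fresh CD4+ and 3353 ± 866 in fresh CD8+ cells. Blnk, Cd79a, Fcer2a and Iglc1 had means below the floor in fresh CD4+ cells. Of the brighter markers, Blk (-1.32), Spib (-1.161), Cd37 (-0.895), Cd79b (-0.215) and Ighm (-0.055) were lower in CD8+ cells. Ms4a1 (1.136), Btk (0.494) and Pax5 (0.047) were higher. The Ighm values argue against B cells in the CD4+ sort alone as the source of the difference. Ighm also had 1691 ± 604 in fresh DN cells, so the sort for high CD11c cannot be taken to have removed all B cells. A difference between the dendritic cell subsets themselves stays open and was not tested. The calls were also lost when single fresh arrays were left out, although for each gene both CD4+ arrays lay above both CD8+ arrays.

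RNA quality was weighed for the 122 calls between fresh CD8+ and fresh CD4+ cells, since fresh CD8+ replicate 1 had a Gapdh 3' to 5' ratio of 2.55. The actin ratio of that array was 0.908, so the 2 controls do not give the same picture of its RNA. Without the 3 arrays of high ratio, in a fit of the same 6159 probe sets that also lost 2 cultured arrays, 109 of the 122 were called again, without fresh CD8+ replicate 1 alone 50, and without fresh CD8+ replicate 2 alone 83, although the median SE was alike in the last 2 fits (0.452 and 0.453). The 50 probe sets called both without the 3 arrays and without fresh CD8+ replicate 1 argue against RNA quality as the cause of those calls. For the other 72, the log2 difference without fresh CD8+ replicate 1 was a median 0.92 times that with it (quartiles 0.85 and 1.02), and RNA quality could still account for some of them, since a call made with both arrays favours probe sets on which the 2 go together. A difference between the subsets themselves remains open as the design's own explanation.

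Fresh DN and CD4+ cells gave 81 probe sets at an unadjusted p under 0.05, fewer than the 308 that chance gives. When the 4 arrays were fitted alone, 499 had such a p. This is consistent with a spread that was shared with noisier groups: the replicates of fresh CD4+ cells differed by an SD of 0.525 on the log2 scale, those of fresh CD8+ cells by 0.95 and those of cultured CD4+ cells by 1.3. The 0 calls between these subsets may therefore understate their difference, since the fit of 4 arrays called 15. A real difference between DN and CD4+ cells was not tested apart from this. The shared spread may also overstate the calls of noisier groups. With only the groups compared, culture in CD4+ cells called 150 higher and 104 lower, against 464 and 669 in the main fit. In DN cells culture called 520 and 658, against 259 and 351, so CD4+ cells no longer had more calls than DN cells. A fit of 4 arrays also has fewer residual degrees of freedom, so it does not show the part of the spread alone.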

How the results depend on the processing

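Most settings were planned, and the tests on the 6 arrays of the same state, on quantile normalization after the filter and without the 3 arrays of high Gapdh ratio were chosen only after the result was seen. Of 218 named calls, 52 lost the call in at least 1 planned setting other than leaving out arrays (2253 values) and 74 in at least 1 fit without an array, and 8 values changed sign. For uncalled lists no direction was given, so only the side of the threshold was judged. Signal over background limited the dim genes, which have only bounds. Where a value moved, the cause was not tested, except that a second threshold can only lower a count.

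Under quantile normalization in both orders, the mean culture effect of H2-K1 became -0.012, H2-D1 -0.14, Rplp0 -0.11 and Rps28 -0.19, and the ribosomal protein list turned, not called (adjusted p = 0.341 and 0.331). H2-Eb1 lost its call (0.153 and 0.156). Quantile normalization after the filter called 189 probe sets between fresh CD8+ and CD4+ cells. The hard floor called 206 there, 134 between fresh CD8+ and DN cells and 1 between cultured DN and CD4+ cells. The filter of 6 arrays called 8 lists between fresh CD8+ and DN cells. Plain eBayes called 1 and 1 for the difference in culture effect of CD8+ against CD4+ and DN cells. Array weights called 1 between fresh DN and CD4+ cells, 30 between cultured CD8+ and CD4+ cells, 182 between cultured CD8+ and DN cells, 717 for culture in CD4+ and 1172 in DN cells. With only the groups compared, the counts were 75 (fresh CD8+ against CD4+), 15 (fresh DN against CD4+), 20 (cultured CD8+ against CD4+), 30 (cultured CD8+ against DN), 254 (culture, CD4+) and 1178 (culture, DN). A 2-fold minimum left 1428 for the mean culture effect. With an estimated correlation, 2, 2, 0 and 0 lists were called for the 3 fresh comparisons and the mean culture effect. The 6 arrays of the same state gave 30 and 4 for cultured CD8+ against CD4+ and DN cells. Without the 3 arrays of high Gapdh ratio, the counts were 161 (fresh CD8+ against DN), 2 (fresh DN against CD4+), 319, 222 and 3 (cultured CD8+ against CD4+, CD8+ against DN and DN against CD4+), 969 (culture, CD8+), 7 and 1 (difference in culture effect, CD8+ and DN each against CD4+) and 13 lists (fresh CD8+ against CD4+). Without those arrays the immediate-early list between cultured DN and CD4+ cells turned, not called (0.776). It turned also without cultured CD4+ replicate 1 (0.53, range without single arrays 0.00206 to 0.53). The interferon list there turned without cultured DN replicate 2 (0.0222, range 7.91e-25 to 0.161).

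With the replicate block, which pairs arrays by experiment number, the counts were 192 (fresh CD8+ against CD4+), 128 (cultured CD8+ against DN), 1786 (culture, CD4+) and 1039 (culture, DN). The immediate-early list between fresh CD8+ and DN cells lost its call (0.0541) and Cd4 between fresh CD8+ and CD4+ cells gained one (0.0488). The block changed no other call of a named gene or list that was run.

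Correlations across genes moved without the filter to 0.744 and 0.637 (culture in DN against CD4+ and CD8+ cells) and 0.313 (CD8+ against DN, fresh with cultured), and without the 3 arrays to 0.787 (culture, CD4+ and DN), 0.451 (CD8+ against CD4+) and 0.155 (DN against CD4+).

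When single arrays were left out, the lone array of the group was assumed to vary like the other groups. Counts ran from 26 to 200, 8 to 123 and 0 to 0 (fresh CD8+ against CD4+, CD8+ against DN, DN against CD4+), 28 to 551, 5 to 158 and 0 to 197 (the same, cultured), 306 to 2102, 131 to 773, 90 to 964 and 1681 to 3123 (culture in CD4+, CD8+ and DN cells and the mean), 0 to 163, 0 to 3 and 0 to 72 (difference in culture effect, same order), and 5 to 12, 5 to 9, 6 to 8 and 5 to 7 lists (fresh comparisons and mean culture effect). Correlations ran from 0.419 to 0.799, 0.729 to 0.82 and 0.543 to 0.781 (culture, CD4+ with CD8+, CD4+ with DN, CD8+ with DN) and from 0.034 to 0.515, 0.197 to 0.514 and -0.125 to 0.11 (fresh with cultured).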

Other observations

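The tests without the 3 arrays of high Gapdh ratio, on the 6 arrays of the same state and on quantile normalization after the filter were chosen only after the result was seen. Culture also moved genes outside the lists that were called. Il1r2, a decoy receptor for interleukin-1, rose (4077 ± 2834 in cultured and 139 ± 95.9 in fresh cells, SD over 6 arrays each, adjusted p = 5.18e-07). Spic, a transcription factor of red pulp macrophages, rose (574 ± 383 against 40.9 ± 39.9, adjusted p = 2.09e-05), and Hmox1, heme oxygenase, rose by 1.81 ± 0.32 on the log2 scale (SE, 2774 ± 2364 against 667 ± 333, adjusted p = 0.0013). The complement gene C1qc was at least 2.47-fold lower (adjusted p = 0.000129). Batf3, a transcription factor of CD8+ dendritic cells, fell by 1.92 (SE 0.20; 437 ± 170.1 against 1567 ± 184, adjusted p = 4.96e-05), and Itgax, which encodes CD11c, fell by 0.86 (SE 0.23; 1390.2 ± 529 against 2468 ± 597, adjusted p = 0.014). Was, the Wiskott-Aldrich syndrome protein, fell by 2.00 (SE 0.17; 211 ± 44.7 against 854 ± 184, adjusted p = 1.49e-05).

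Lists that did not pass for the mean culture effect are given as counts of genes higher and lower. Immediate-early genes had 8 and 16 of 31 (adjusted p = 0.183), with Egr1, Jun and Rhob among the lower ones. CD8+ dendritic cell markers had 2 and 3 of 13 (0.583), CD8-negative markers 4 and 9 of 17 (0.283), MHC class I 4 and 3 of 13 (0.467) and MHC class II 6 and 5 of 21 (0.501; median -0.25, mean 0.03). Toll-like receptors had 3 and 2 of 7 (0.485), heat shock genes 5 and 4 of 28 (0.307) and glycolysis genes 4 and 2 of 13 (0.498). Oxidative phosphorylation had 1 and 10 of 44 (0.0683) and passed, lower, under quantile normalization (0.027). Chemokine receptors had 4 and 2 of 13 (0.183), integrins 6 and 8 of 25 (0.501), actin genes 10 and 3 of 36 (0.467; median -0.02, mean 0.09), complement and Fc receptors 1 and 6 of 15 (0.482) and apoptosis regulators 11 and 6 of 24 (0.172).

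Markers of other cells were measured in the same way. For the mean culture effect, T cell markers had 2 higher and 0 lower of 5 (adjusted p = 0.24), B cell markers 2 and 6 of 14 (0.498), plasma cell markers 3 and 0 of 6 (0.331), plasmacytoid dendritic cell markers 1 and 2 of 11 (0.849; median 0.21, mean -0.03), NK cell markers 2 and 1 of 7 (0.583), macrophage markers 4 and 7 of 17 (0.66), neutrophil markers 1 and 2 of 7 (0.683), red cell markers 2 and 0 of 6 (0.24) and stromal markers 2 and 1 of 9 (0.331). Platelet markers (1 and 1 of 4) and basophil or mast cell markers (0 and 0 of 3) had too few measured genes for the test. Between cultured CD8+ and DN cells, macrophage markers were higher (2 higher, 0 lower of 17; 6 and 1 adjusted over the list alone). This list had adjusted p = 0.000766, but adjusted p = 0.0521 with an estimated correlation. Between cultured CD8+ and CD4+ cells, NK cell markers were lower (0 of 7 called, 2 lower adjusted over the list alone). Tested as a list, they had adjusted p = 0.00778, but adjusted p = 0.316 with an estimated correlation, 0.111 without cultured CD4+ replicate 1 and 0.0929 without the 3 arrays of high Gapdh ratio. Against cultured DN cells they were lower too (1 of 7; 1 adjusted over the list alone). The preset correlation gave adjusted p = 0.0178, but adjusted p = 0.405 with an estimated correlation. That call was lost without cultured CD8+ replicate 2 (0.088), cultured DN replicate 1 (0.151) or the 3 arrays of high Gapdh ratio (0.279), with a hard floor (0.0515) and with a filter of 6 arrays (0.0921). Oxidative phosphorylation genes were also higher in cultured CD8+ than in CD4+ cells (0 of 44 called, also adjusted over the list alone). As a list, these genes had adjusted p = 1.47e-05, but adjusted p = 0.316 with an estimated correlation.

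Between cultured DN and CD4+ cells, where 0 members of any list were called over all genes, 5 lists passed with the preset correlation. With an estimated correlation, adjusted p = 0.719 for oxidative phosphorylation, cell cycle and macrophage genes and adjusted p = 0.931 for the other lists. Oxidative phosphorylation genes were higher (median 0.33, 0 of 44 adjusted over the list alone, adjusted p = 0.000307), a call lost without cultured CD4+ replicate 1 (0.193) or cultured DN replicate 2 (0.149). Cell cycle genes were higher (median 0.32, 0 of 43 adjusted over the list alone, adjusted p = 0.0057), a call lost without cultured CD4+ replicate 1 (0.0873) or 2 (0.0809), cultured DN replicate 2 (0.0787), the 3 arrays of high Gapdh ratio (0.102), or with a hard floor (0.238). Interferon-induced genes were lower (median -0.62, 1 of 25 higher adjusted over the list alone, adjusted p = 0.000307), but the call was lost without cultured CD4+ replicate 2 (0.161) and turned to higher without cultured DN replicate 2 (0.0222). Macrophage markers were lower (median -0.16, 1 of 17 lower adjusted over the list alone, adjusted p = 0.0244), a call lost without cultured CD4+ replicate 1 (0.0873) or 2 (0.239). Immediate-early genes were lower (median -0.15, 0 of 31 adjusted over the list alone, adjusted p = 0.0408). That call was lost under quantile normalization (0.0681, and 0.0751 after the filter), with a hard floor (0.143), with the 6 arrays of the same state (0.0577) and without cultured DN replicate 2 (0.158). Its direction turned, not called, without cultured CD4+ replicate 1 (0.53) and without the 3 arrays of high Gapdh ratio (0.776).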
